A study of Mus musculus with 8 samples.

How the data were processed

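The series profiled RNA of pancreatic beta cells that were flow-sorted from islets of tamoxifen-treated mice. Per the labels, 4 libraries came from Control mice and 4 from mice in which Chd4 was deleted in beta cells, called Chd4KO here. Each library carries its own animal number in the labels, so replicates were taken as separate mice. The animal numbers are lower in every Control library than in every Chd4KO library. The labels do not say whether they mark litters, ages or days of collection, and any such difference cannot be told apart from genotype. Per the labels' protocols, RNA that passed an RNA integrity minimum was turned into cDNA with a low-input SMART-Seq kit and into libraries with a Nextera XT kit. Such libraries do not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

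The authors deposited 1 table per library with TPM, transcripts scaled to a fixed total, for 55487 Ensembl gene identifiers, and each table summed to the same fixed total. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2, HTSeq and DESeq2 were used with the mouse build mm10, without versions or roles. The annotation release is not given in the sources used here. Symbols, positions and gene lengths were taken from GENCODE M21, which has the same build, and 55227 of the 55487 identifiers (99.5%) were found in it. Because TPM is scaled to a fixed total, a larger share taken by a few transcripts, such as insulin, lowers the value of every other gene in that library.

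TPM tables hold no read numbers. TPM multiplied by the length of a gene's merged exons was a whole multiple of a single step in each library for 98.5 to 98.7% of the values above 0, with a tolerance of 0.05 of a read. Whole reads per gene were recovered that way and were used for depth, for thinning and for an alternative test. They were not used in the main test, which was chosen for TPM.

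The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with genotype as the only term, no variance trend, and two-sided p-values adjusted by the Benjamini-Hochberg method. Genes with a TPM of at least 1 in at least 4 libraries were tested, and an adjusted p under 0.05 was called a change. A gene under 1 TPM in every library of 1 group was tested only if all 4 libraries of the other reached 1 TPM. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM, and their errors are limma's standard errors. The named-gene rule, the 27 gene lists, the main test and most alternatives were fixed before the data were examined. For comparisons of a single value between the groups an exact permutation test was used, which with 4 against 4 libraries cannot give a two-sided p below 0.0286. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

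The genes named are Chd4, the islet hormones Ins1, Ins2, Gcg, Sst and Ppy, and Xist. Added to these are the 12 genes with the largest positive and the 12 with the largest negative change among called genes with a mean TPM of at least 5 and no overlap between the groups, leaving out predicted genes, pseudogenes and unnamed identifiers. From each gene list come up to 4 called members with the smallest adjusted p and, where at most 1 member was called, the 2 tested members with the highest TPM. The 23 lists with at least 5 tested members were tested as sets with limma's camera at a preset correlation between genes of 0.01, then with an estimated correlation, and with fry, for a shift in 1 direction and for changes in either direction. Lists of endothelial, mesenchymal and glial, erythroid and sex-linked genes had fewer than 5 tested members or served to check the samples, and were not tested as sets. List counts are given over all genes tested and adjusted over the list alone.

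The fit was tested on simulated data with 200 changed genes in each of 5 runs of 4 against 4 libraries, on 15204.6 genes on average. It recovered 0.299% of genes changed 1.5-fold, 10.2% of those changed 2-fold and 64.2% of those changed 4-fold. Of its calls 7.14% were false, and 5 runs with no change gave 0 calls. The changed genes were drawn from those with a mean TPM of at least 5, and genes varied independently of each other. Under these settings most changes of 2-fold or less were missed. Recovery in the real data may differ, since it depends on how many genes change.

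Alternatives covered a pseudocount of 0.1, no filter, a minimum TPM of 5, scaling by the median of ratios, scaling without islet hormones and mitochondrial genes, quantile normalisation, a variance trend with robust estimation, array weights, a replicate block, a minimum absolute log2 change of 1, and leaving out each library. Scaling by trimmed means was replaced by the median of ratios, as the plan allowed. Negative binomial tests were planned only for count files and were not run. After the data had been seen, limma's voom on the recovered reads and a fit without 2 libraries that stood apart were added. The 4 gene lists tested at the end were also chosen after the data had been seen.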

Results

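RNA sequencing measured transcript levels in beta cells, the insulin-secreting cells of the pancreatic islet, from 4 Control and 4 Chd4KO mice. Chd4 is a helicase that moves nucleosomes and is the motor subunit of the NuRD complex, which also carries histone deacetylases. Reads in genes, recovered from TPM and gene length, numbered 29.5 ± 10.7 M in Control libraries (SD, n = 4) and 16.8 ± 2.39 M in Chd4KO libraries (SD, n = 4). The range was 16.4 to 41.0 M in Control and 14.9 to 20.2 M in Chd4KO (exact permutation p = 0.0857, two-sided). Replicates of a group correlated at 0.870 to 0.985 across genes on the log2 scale.

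Insulin transcripts took a large part of every library. Ins1 and Ins2 together made up 40.2% ± 1.58 of TPM in Control and 44.4% ± 13.2 in Chd4KO (SD, n = 4 each, exact permutation p = 0.657). The share reached 62.0% in Chd4KO replicate 4, where 12702 genes had a TPM of at least 1, against 14788 to 15923 genes in the other 7 libraries. Markers of acinar cells, the enzyme-secreting cells around the islets, stood out in Chd4KO replicate 2. Their 15 tested members summed to 42769 TPM there, to 1718 TPM in Control replicate 2, and to between 2.63 and 249 TPM in the other 6 libraries. Xist, transcribed from the inactive X chromosome, did not exceed 0.0618 TPM in any library, and the Y-linked gene Eif2s3y lay between 11.3 and 37.3 TPM.

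**Figure D1:**
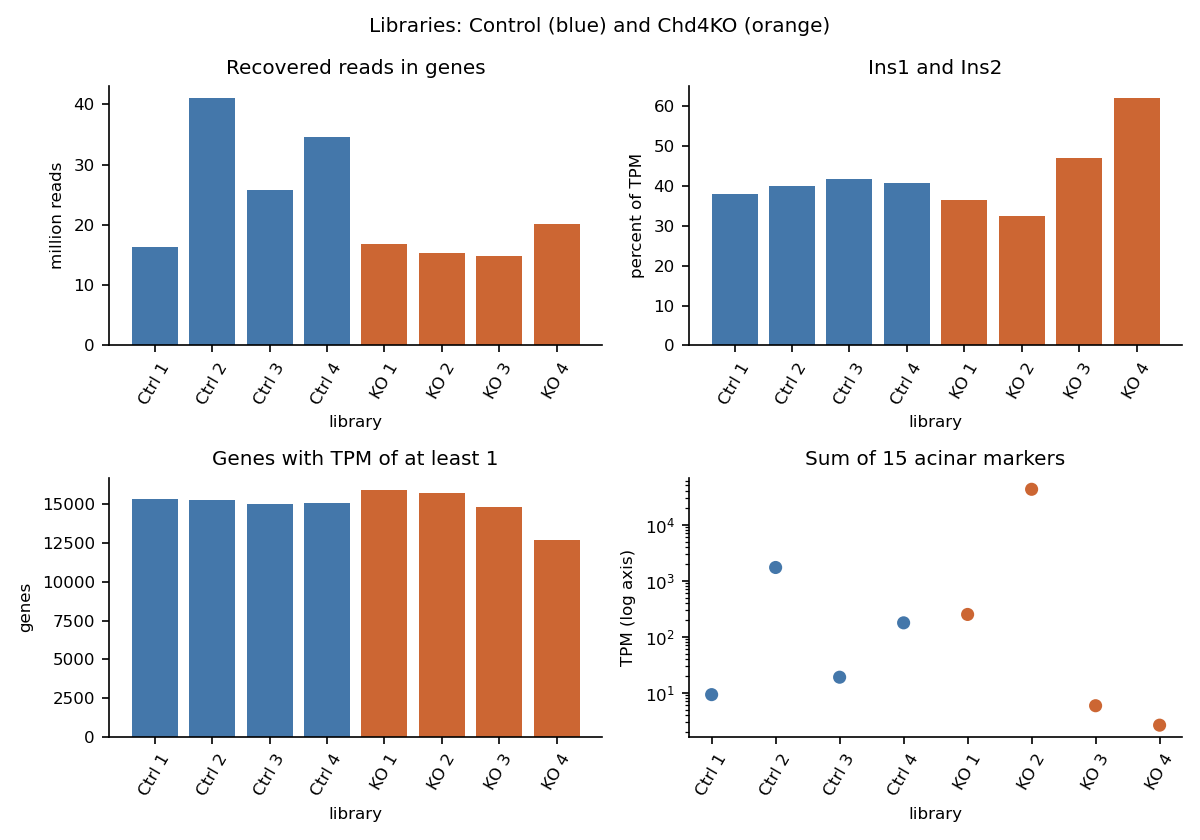
Depth and composition of the 8 libraries, with Control in blue and Chd4KO in orange: bars give recovered reads in genes, the percent of TPM from Ins1 and Ins2 and the number of genes with a TPM of at least 1, and points give the summed TPM of 15 acinar markers on a log axis. Chd4KO replicate 4 has the highest insulin share, 62.0%, and the fewest genes, 12702, and Chd4KO replicate 2 has the highest acinar sum, 42769 TPM.

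The comparison of Chd4KO with Control asked how gene expression in beta cells differs once Chd4 is deleted there. Chd4 itself (ENSMUSG00000063870, mm10 chromosome 6, 125095981 to 125130591) had a TPM of 15.98, 13.4, 11.1 and 12.3 in Control replicates 1 to 4. In Chd4KO replicates 1 to 4 it had a TPM of 8.38, 6.18, 5.27 and 2.59. The means were 13.2 ± 2.08 and 5.604 ± 2.40 TPM (SD, n = 4 each), so Chd4KO kept 42.4% of the Control mean. All 4 knockout values lay below all Control values (exact permutation p = 0.0286, the smallest that 4 against 4 allows). In the fit across all genes the Chd4 change was -1.18 ± 0.29 (log2, SE), with an adjusted p of 0.0725 from limma, outside the threshold. That adjusted p lay between 0.00782 and 0.215 over 19 alternatives and was under the threshold in 6 of them. The files give 1 value per gene, so reads from exons outside a deleted part cannot be separated.

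In Chd4KO beta cells the serotonin-synthesis enzyme Tph1, the transcription factor Mafa, the glucose transporter Slc2a2 and the granule protein Chga fell, while C1qtnf1, Gpbar1, Cd81, Ambp and Rbp4 rose. The insulin genes Ins1 and Ins2 and the other islet hormones Gcg, Sst and Ppy did not pass the test. Of the genes that changed here, Mafa kept its call in 14 of 19 alternatives, Chga in 13, Rbp4 in 11 and Slc2a2 in 10, and Tph1, C1qtnf1, Gpbar1, Cd81 and Ambp in each that tested them. Gpbar1 was tested in 14 of the alternatives, none of which left out a Chd4KO library. Of 15189 genes tested with limma, 451 changed at an adjusted p under 0.05, with 233 higher and 218 lower in Chd4KO, and 2460 had an unadjusted p under 0.05. The groups did not overlap in 450 of the 451, nor in 2252 of all tested genes (14.8%). For a single gene whose libraries are interchangeable, the chance of no overlap is 2.86%. That is no test of the share, since all genes come from the same libraries and vary together. The filter shapes the share too, since a gene under 1 TPM throughout 1 group was tested only if the groups did not overlap. The median change of all tested genes was -0.25 (log2), a shift that came to -0.06 without Chd4KO replicate 4 and to -0.01 with median-of-ratios scaling. Changes relative to that median are given where the shift matters. All 451 genes kept their direction under the 3 other scalings of TPM, but the balance moved, with 445 higher and 255 lower genes under median-of-ratios scaling and 466 and 289 under quantile normalisation, against 351 and 314 when hormones and mitochondrial genes were left out of the scaling. Leaving out Control replicates 1 to 4 in turn gave 199 genes (140 higher, 59 lower), 160 (123, 37), 192 (131, 61) and 144 (106, 38). Leaving out Chd4KO replicates 1 to 4 gave 246 (91 higher, 155 lower), 244 (95, 149), 135 (63, 72) and 630 (300, 330). The filter still asked for 4 libraries in these fits, so genes that reached it only in the reduced group could not be tested. Of the 451 main calls, 414 were tested without a Control library and 352 without a Chd4KO library. The balance of higher and lower genes in these fits therefore depends partly on the filter.

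**Figure D2:**
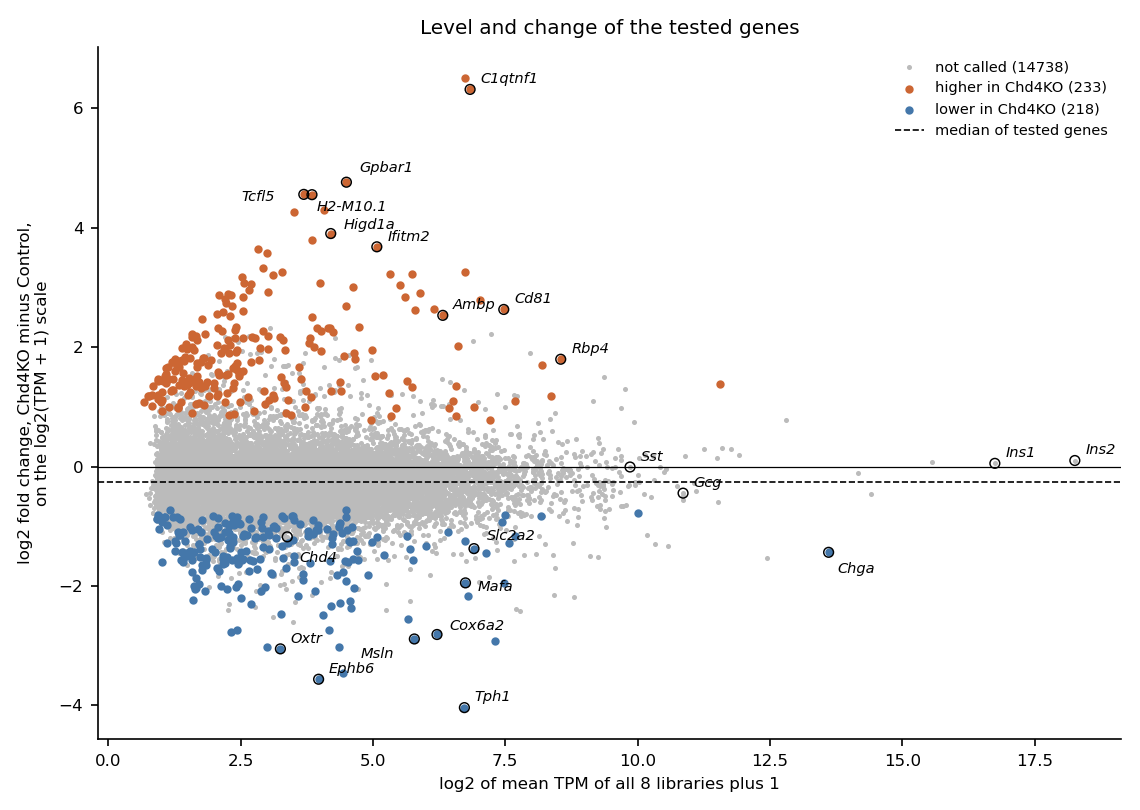
Each point is a tested gene, with the log2 of its mean TPM plus 1 over all 8 libraries on the x axis and the log2 fold change (Chd4KO minus Control, on the log2(TPM + 1) scale) on the y axis. The 233 higher genes are orange, the 218 lower genes are blue, the dashed line marks the median of tested genes at -0.25, and circled genes are named in the text.

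Many of the genes that rose were scarcely transcribed in Control beta cells. Of the 233 higher genes, 117 (50.2%) had a mean Control TPM under 1 and 32 had one of at least 10. The filter shapes the first share, since a gene low in both Control and Chd4KO was not tested. C1qtnf1, a secreted protein of the C1q and TNF family (chromosome 11, 118428203 to 118449963), rose from 1.34 ± 0.204 to 225 ± 157 TPM (SD, n = 4 each), a log2 change of 6.32 ± 0.45 (SE, limma adjusted p = 0.00035). It overlaps Gm11747 on the opposite strand, which rose by 6.50 and whose reads cannot be told apart from it. Gpbar1, a receptor for bile acids, rose from 0.524 ± 0.428 to 42.6 ± 18.03 TPM, and Higd1a, a mitochondrial protein induced by hypoxia, from 1.16 ± 0.359 to 33.6 ± 13.6 TPM. H2-M10.1, an MHC class I gene of a family with close copies, was listed at 0 in all 4 Control libraries and lay between 11.98 and 29.7 TPM in Chd4KO. Tcfl5, a transcription factor of the germ line whose end overlaps Col9a3, rose from 0.0889 ± 0.0352 to 26.7 ± 12.8 TPM. The glutathione enzymes Gpx6 and Gstm3 rose from 0.0493 ± 0.0986 to 20.6 ± 9.38 TPM and from 0.366 ± 0.192 to 12.8 ± 3.06 TPM. Ugt1a1, which conjugates bilirubin, rose from 0.823 ± 0.304 to 25.8 ± 10.5 TPM, a value left uncertain because genes of its locus share exons. Ifitm2, an interferon-induced membrane protein, rose from 4.07 ± 1.72 to 61.2 ± 12.7 TPM, and the GABA transporter Slc6a13 from 0.0333 ± 0.0389 to 12.2 ± 3.81 TPM. The matrix genes Bcan and Col5a3 rose from 0.0582 ± 0.0549 and 0.0380 ± 0.0356 TPM to 13.9 ± 10.05 and 31.6 ± 31.3 TPM, and Col5a3 spanned 3.36 to 73.7 TPM over the knockout libraries and kept its call in 8 of the 13 alternatives that tested it.

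Of the 218 lower genes, 58 (26.6%) had a mean Chd4KO TPM under 1, and 99 had a mean Control TPM of at least 10. The filter shapes the first share here too, since genes low in both groups were not tested. Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, fell from 196 ± 96.9 to 14.0 ± 14.4 TPM (SD, n = 4 each), a log2 change of -4.04 ± 0.60 (SE, limma adjusted p = 0.00845). The receptor genes Ephb6 and Oxtr, which bind ephrins and oxytocin, fell from 28.2 ± 23.4 to 1.201 ± 1.05 TPM and from 15.9 ± 4.69 to 1.13 ± 0.882 TPM. Msln, which encodes the surface protein mesothelin, fell from 96.5 ± 46.1 to 11.4 ± 2.62 TPM. Cox6a2, a subunit of cytochrome c oxidase otherwise found in muscle, fell from 126 ± 19.95 to 19.8 ± 14.1 TPM. Prok1, a secreted peptide, fell from 30.0 ± 14.99 to 3.88 ± 2.57 TPM, and the antisense gene A630076J17Rik over the same span fell by 3.03 (log2). The insulin-like growth factor binding protein Igfbp5 fell from 27.3 ± 15.6 to 3.82 ± 1.81 TPM and the orphan receptor Gpr27 from 38.7 ± 7.64 to 6.97 ± 2.61 TPM. Srbd1, Cyp4f39, Sdsl and Lrrn2 completed the 12, with log2 changes of -2.55, -2.34, -2.30 and -2.24. Over 19 alternatives Ephb6 kept its call in 18, Prok1 in 17, Srbd1 in 12 and Igfbp5 in 11.

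**Figure D3:**
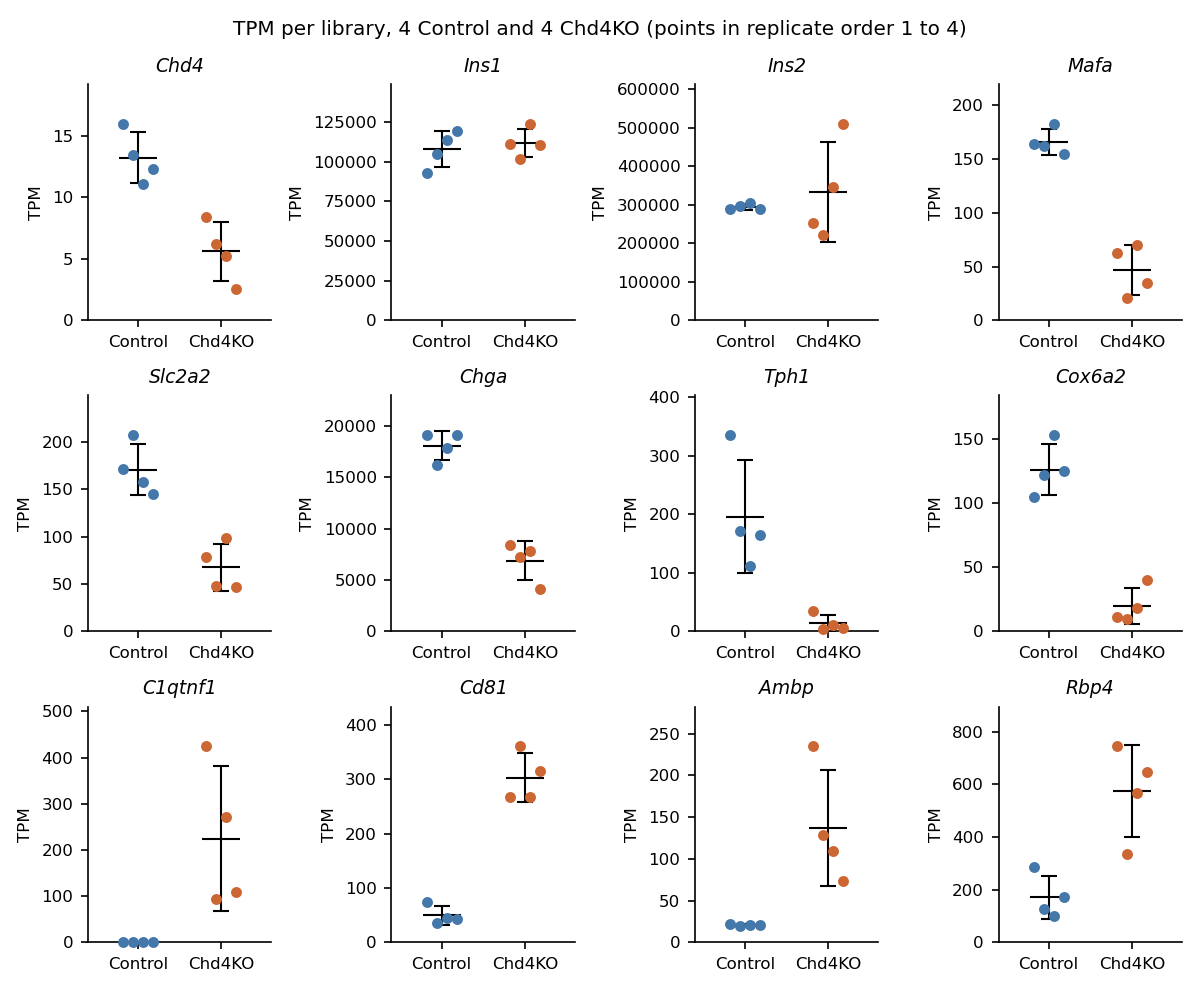
TPM of 12 genes in each of the 4 Control libraries (blue) and 4 Chd4KO libraries (orange), on linear axes that start at 0; bars give the mean and SD of each group. The groups do not overlap for any of the genes shown except Ins1 and Ins2, whose changes were 0.05 and 0.10 (log2).

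Among 23 tested transcription factors of the beta cell, Mafa fell and 22 did not pass; adjusted over the list alone, 2 fell. Mafa, which activates the insulin genes in mature beta cells, went from 166 ± 11.99 to 47.0 ± 23.3 TPM (SD, n = 4 each), a log2 change of -1.95 ± 0.36 (SE, limma adjusted p = 0.0229) and of -1.69 relative to the median gene. Neurod1 was at 186 ± 26.2 and 144 ± 59.6 TPM (adjusted p = 0.484). Among 15 markers of mature beta cells, Cox6a2, Mafa and Slc2a2 fell, Nnat rose and 11 did not pass; adjusted over the list alone, 8 fell and 1 rose. Slc2a2, the glucose transporter of rodent beta cells, fell from 170.3 ± 26.9 to 67.8 ± 24.8 TPM (log2 change -1.37 ± 0.27, adjusted p = 0.031, and -1.12 relative to the median gene). Nnat, the imprinted gene of neuronatin, went the other way, from 3.06 ± 1.05 to 23.7 ± 12.6 TPM (log2 change 2.51 ± 0.37, adjusted p = 0.00845), and the small gene Gm23134 that overlaps it rose as well. As a set, the mature markers lay lower than other genes with a median 0.65 below that of all tested genes (camera adjusted p = 0.00831), but not with an estimated correlation (adjusted p = 0.926). The list of glucose sensing and excitation had Cox6a2 and Slc2a2 as its only called members out of 21; adjusted over the list alone, 3 fell (camera adjusted p = 0.0717).

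Markers of immature and progenitor cells moved both ways, with Cd81 and Mycl higher, Npy lower and 6 of 9 not passing; adjusted over the list alone the count was the same, 2 higher and 1 lower (camera adjusted p = 0.107). Cd81, a tetraspanin of the cell surface, rose from 49.6 ± 17.2 to 303 ± 45.1 TPM (SD, n = 4 each; log2 change 2.63 ± 0.25, limma adjusted p = 0.00119). Mycl, a MYC-family factor, rose from 0.488 ± 0.318 to 2.88 ± 1.18 TPM. It was under 1 TPM in every Control library and passed the filter only through its Chd4KO values. Npy, a neuropeptide, fell from 8.28 ± 4.55 to 1.10 ± 1.09 TPM. Mycl kept its call in 7 of the 13 alternatives that tested it and Npy in 8 of 18. Of 26 genes that mature beta cells keep low, 5 reached the filter. Members that stay low in both groups were left out, so the tested members lean towards those that rose. Gas6, a ligand of TAM receptors, rose from 1.41 ± 0.534 to 9.70 ± 1.998 TPM (log2 change 2.16 ± 0.23, adjusted p = 0.00147), and adjusted over the list alone 2 rose. Oat was at 11.1 ± 5.56 and 39.0 ± 19.7 TPM (adjusted p = 0.0731), Zyx at 10.4 ± 4.71 and 12.9 ± 11.2 TPM. This list lay higher than other genes (camera adjusted p = 0.00225), but not with an estimated correlation (adjusted p = 0.206). The leaning of the filter towards risen members bears on this set result.

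The insulin genes did not pass the test, which does not show that their level was kept. Ins2 spread widely in Chd4KO, from 221730 to 509590 TPM, on both sides of the Control range of 287650 to 304130 TPM. Ins1 was at 107970 ± 11560 TPM in Control and 111860 ± 9035 TPM in Chd4KO (SD, n = 4 each; log2 change 0.05 ± 0.17, limma adjusted p = 0.869). Ins2 was at 294020 ± 7577 and 332580 ± 129220 TPM (0.10 ± 0.26, adjusted p = 0.843), and the 2 changes were 0.31 and 0.35 relative to the median gene. Ins1 and Ins2 are close copies, so their reads may be split between them. Of 15 genes of insulin production and processing, Sil1 fell and 14 did not pass, and 1 fell adjusted over the list alone (camera adjusted p = 0.912). Sil1, a cofactor of the endoplasmic reticulum chaperone BiP, fell from 91.0 ± 8.55 to 35.5 ± 2.91 TPM (-1.33 ± 0.16, adjusted p = 0.0033); antisense genes overlap its span. Of 24 genes of secretory granules and exocytosis, Chga fell and 23 did not pass, and 1 fell adjusted over the list alone (camera adjusted p = 0.627). Chga, which encodes the granule protein chromogranin A, fell from 18048 ± 1398 to 6888 ± 1883 TPM (-1.44 ± 0.24, adjusted p = 0.0155, and -1.18 relative to the median gene). Scg2, a related granin, was at 4942 ± 558 and 9373 ± 4442 TPM (adjusted p = 0.336).

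Hormones of other islet cells did not pass the test. Gcg of alpha cells was at 1915 ± 537 TPM in Control and 1792 ± 1508 TPM in Chd4KO (SD, n = 4 each; limma adjusted p = 0.673). Sst of delta cells was at 930.4 ± 307 and 919 ± 254 TPM (adjusted p = 0.99) and Ppy of PP cells at 2140 ± 752 and 1566 ± 877 TPM (adjusted p = 0.523). None of 7 alpha cell markers was called, among them Ttr at 212 ± 87.2 and 192 ± 39.7 TPM; adjusted over the list alone 1 rose (camera adjusted p = 0.462). Of 5 markers of delta, PP and epsilon cells, Rbp4, a carrier of retinol that is also made in liver, rose from 170.7 ± 81.3 to 575 ± 174 TPM (log2 change 1.80 ± 0.36, adjusted p = 0.033), and 1 rose adjusted over the list alone (camera adjusted p = 0.462). Of 7 ductal markers, Ambp, a plasma protein precursor, rose from 20.8 ± 1.27 to 137 ± 69.7 TPM (2.53 ± 0.32, adjusted p = 0.00388). The chloride channel gene Cftr fell from 4.04 ± 2.85 to 0.251 ± 0.218 TPM (-1.87 ± 0.35, adjusted p = 0.0238), a call kept in 10 of the 14 alternatives that tested it, and adjusted over the list alone 1 ductal marker rose and 2 fell (camera adjusted p = 0.561).

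Markers of cells from outside the islet were measured to describe the sort. None of 15 acinar markers was called over all genes or adjusted over the list alone. Prss2 was at 80.7 ± 142 and 1868 ± 3711 TPM and Try4 at 45.1 ± 78.1 and 1689 ± 3360 TPM (SD, n = 4 each). As a set the acinar markers lay higher than other genes (camera adjusted p = 0.0162), not with an estimated correlation (adjusted p = 0.937). Without Chd4KO replicate 2 their median change turned from 0.97 to -1.53, over the 10 markers that still passed the filter. Of 10 leukocyte markers, Cd68 rose from 1.55 ± 0.425 to 4.91 ± 0.791 TPM (limma adjusted p = 0.0132) and Fcer1g from 15.8 ± 5.36 to 48.1 ± 16.97 TPM (adjusted p = 0.0482), and 3 rose adjusted over the list alone. Both genes encode proteins abundant in myeloid cells, and Fcer1g kept its call in 7 of 19 alternatives (highest adjusted p = 0.171), Cd68 in 15 of 18. That list lay higher as a set (camera adjusted p = 0.00528), not with an estimated correlation (adjusted p = 0.312), and Ptprc, the common leukocyte antigen, was below the filter at mean values of 0.351 and 0.0857 TPM. The highest value of any endothelial marker in any library was 4.37 TPM and of any erythroid marker 13.6 TPM, and none of their 2 and 2 tested members was called. Among these were Egfl7 at 1.30 ± 0.1798 and 2.88 ± 0.6996 TPM (adjusted p = 0.0733), Esam at 4.10 ± 0.204 and 3.32 ± 0.609 TPM and Hba-a1 at 5.12 ± 5.69 and 5.69 ± 2.995 TPM. Of the 4 tested sex-linked genes none was called, with Ddx3y at 24.9 ± 2.51 and 18.2 ± 10.2 TPM.

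The NuRD list and lists of stress, growth and metabolism held no called member. None of 15 NuRD subunits and CHD paralogs, a list that holds Chd4, was called over all genes. Chd4 was the 1 that fell adjusted over the list alone, and Mbd2 was at 96.4 ± 9.50 and 100.3 ± 21.7 TPM (SD, n = 4 each; camera adjusted p = 0.627 for the list). The 22 genes of the unfolded protein response (camera adjusted p = 0.827) included the chaperone Hspa5 at 2255 ± 527 and 2032 ± 1136 TPM. The 25 cell cycle genes (camera adjusted p = 0.484) included Ccnd2 at 175.5 ± 21.3 and 148 ± 32.4 TPM, and the 15 p53 targets and cell cycle inhibitors (camera adjusted p = 0.459) included Btg2 at 868 ± 402 and 349.7 ± 289.6 TPM. Of 15 immediate early genes, which respond to cell dissociation, Fos was at 1932 ± 985 and 1097 ± 1011 TPM (camera adjusted p = 0.462 for the list). The 25 nuclear genes of oxidative phosphorylation (camera adjusted p = 0.0911) included Ndufa1 at 446 ± 40.5 and 516 ± 155 TPM. The 15 genes of cholesterol synthesis (camera adjusted p = 0.462) included Sqle at 116 ± 11.2 and 102 ± 36.3 TPM, and the 13 neuronal genes (camera adjusted p = 0.212) included Syp at 173 ± 14.6 and 175 ± 77.9 TPM. No member of these 7 lists passed when adjusted over the list alone.

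A further 3 lists passed camera without a called member. The 13 mitochondrially encoded genes lay lower than other genes (camera adjusted p = 0.0222), not with an estimated correlation (adjusted p = 0.937), and mt-Cytb was at 2507 ± 490.2 and 1896 ± 372 TPM (SD, n = 4 each). The 16 tested genes of interferon response and antigen presentation lay higher (camera adjusted p = 0.0162), not with an estimated correlation (adjusted p = 0.937). H2-D1 among them was at 486 ± 23.5 and 735 ± 328 TPM, and without Chd4KO replicate 1 the list's median change turned from 0.35 to -0.40. The 6 tested genes of striated muscle lay higher (camera adjusted p = 0.00214), not with an estimated correlation (adjusted p = 0.312), with Mylpf at 3.29 ± 1.03 and 9.53 ± 3.85 TPM (limma adjusted p = 0.0533) and Actn2 at 19.1 ± 4.97 and 13.9 ± 7.36 TPM; 1 rose adjusted over the list alone. In all, 7 of 23 lists passed camera at its preset correlation and 0 with an estimated correlation. With fry, 0 lists passed the test for a shift in 1 direction, and 8 passed the mixed test for changes in either direction, led by immature and progenitor markers (adjusted p = 2.5e-07), mature beta cell markers (4.52e-05), ductal markers (7.14e-05) and insulin production (0.000394). A few strongly changed members can carry the mixed test: of the 15 insulin production genes only Sil1 was called. At least 7 lists passed camera in 25 of the 35 ways to split the 8 libraries into 4 and 4, so the camera calls were not beyond chance. For the gene calls no other split gave more than 14. The splits were not run with fry, so its mixed-test results have no such check. The direction of the set test differed from the sign of the list's median in 8 lists and of its mean in 6, and in 2 lists once the median of all tested genes was taken off.

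**Figure D4:**
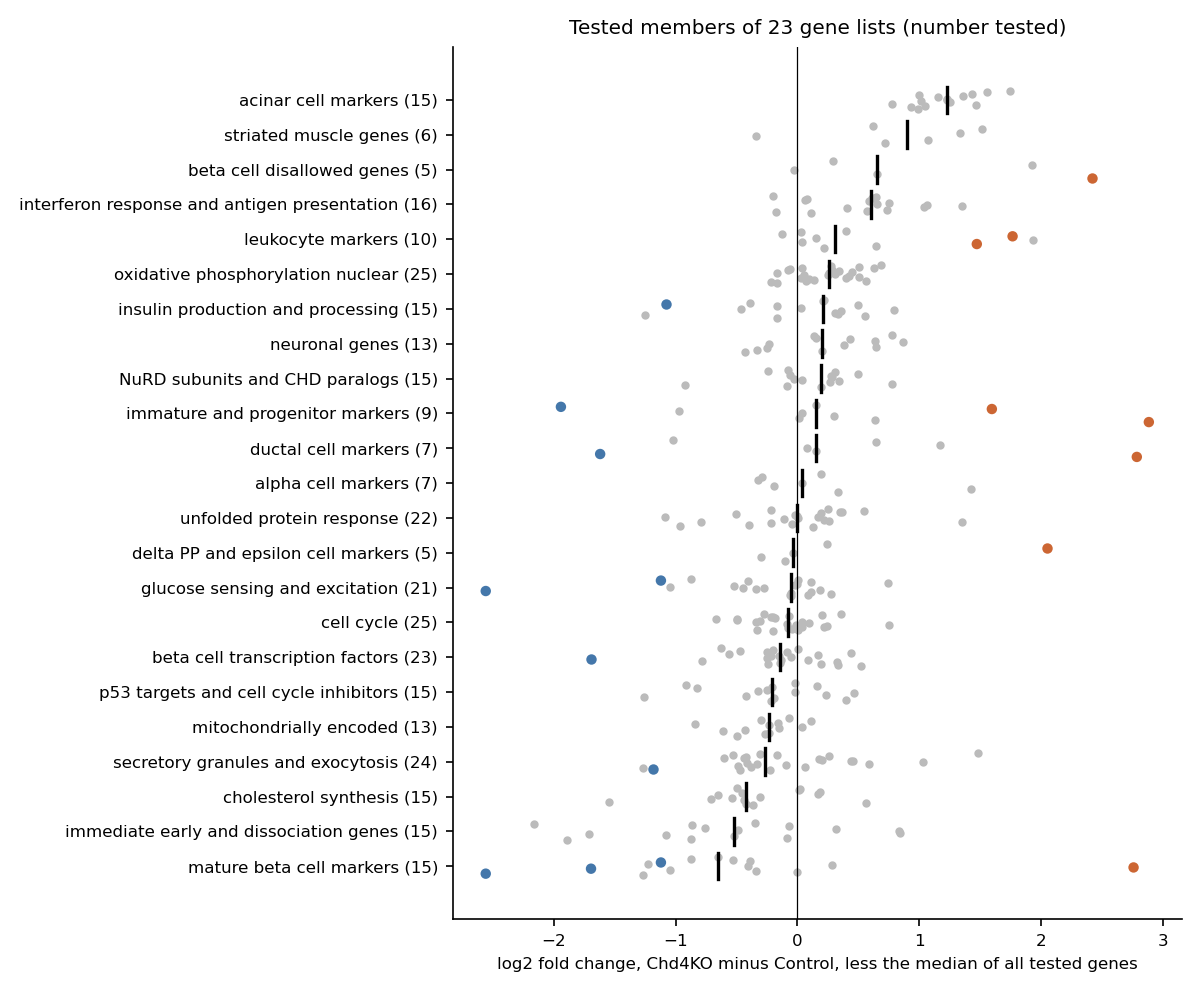
Each point is a tested member of a gene list, placed by its log2 fold change (Chd4KO minus Control) less the median of all tested genes. Orange and blue points are called higher and lower, grey points did not pass, and black bars are list medians, which run from -0.65 for mature beta cell markers to 1.22 for acinar markers.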

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

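The tests on acinar transcripts, and a comparison with Chd4KO replicate 3 on depth, were chosen after the values had been seen. A library was singled out where its gap to the nearest of the other 3 in its group, as a part of the group's range, exceeded Dixon's critical value at 1 in 20. Of 172 groups of 4 values 7 met this, fewer than the 8.6 that chance gives. Gpx6 stood at 0.197 TPM in Control replicate 2 and was listed at 0 in the other Control libraries. Ifitm2 was at 1.51 TPM in Control replicate 1, against 4.69 to 5.21 TPM in the other 3. Igfbp5 was at 1.18 TPM in Chd4KO replicate 4, against 4.31 to 5.26 TPM. Hba-a1 was at 13.6 TPM in Control replicate 3, against 1.91 to 2.47 TPM. In that library mt-Co1 was at 1533 TPM, against 2276 to 2371 TPM, and mitochondrial genes took 0.836% of TPM, against 1.16 to 1.17%. Mitochondrial genes took 1.15% of TPM in Chd4KO replicate 2, against 0.704 to 0.756% in the other knockout libraries.

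Whether any grouping of the libraries gives such counts was tested on all 35 splits of the 8 libraries into 4 and 4. The real split gave 451 changed genes, 233 higher and 218 lower, and the highest other split gave 14. In each case 1 of 35 splits reached the real count, the smallest share that 35 splits can give. The higher and lower counts come from the same split as the total, so they are not separate evidence. A difference that follows the animal numbers rather than genotype would give the same result. For gene lists tested with camera, 25 of the 35 splits gave at least the 7 lists of the real split and the highest other gave 12, so chance cannot be excluded.

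Chd4KO replicate 4 had fewer genes and lower levels than the other 3 knockout libraries, with a median log2 ratio to them of -0.77. Leaving hormones and mitochondrial genes out of the scaling brought this to -0.29 (bootstrap 95% interval over genes -0.31 to -0.28), so the larger insulin share is not the whole cause. Thinned to the same number of reads outside the hormones, the library had the fewest genes with at least 1 read, 21031 against 21980 to 23596, or 95.7% of the lowest other, but not with at least 5 reads, where Control replicate 1 had fewer, 16732 against 16836. That met the bound for depth as a cause that was set in advance, 95% of the lowest other library, here Control replicate 1. Depth may therefore account for part of the lower gene number against that library. The thinning did not test the lower levels or the number of genes with a TPM of at least 1. Chd4KO replicate 3, compared only after that result, had fewer such reads, 10.3 against 10.5 M, and more genes, 22451, which argues against depth alone. Before thinning, the genes above 0 numbered 22498 in replicate 3 and 21095 in replicate 4, so thinning left the gap between these 2 much as it was. Long genes were lower in replicate 4 (Spearman rho of exon length and ratio -0.35, against 0.08 to 0.26 in the other knockout libraries), as a loss of long transcripts would give. Each ratio is to the other 3 knockout libraries, so the rho values of replicates 1 to 3 include replicate 4 and are no independent baseline. Chd4 was lowest in replicate 4, at 2.59 TPM, but lower levels across that library would lower Chd4 as well. A stronger deletion there stays open and untested.

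Acinar transcripts were high in Chd4KO replicate 2, with Prss2 at 7434.5, Try4 at 6729 and Ctrb1 at 6294 TPM. All 15 markers were highest in that library, and their log2 ratio to Control replicate 2, the next highest library, was 4.51 on average with an SD of 0.38 over the markers. Such a constant ratio is consistent with carry-over of acinar cells or RNA past a sort for beta cells, as a hypothesis. A switching-on of acinar genes by loss of Chd4 in that library alone cannot be told apart from this, because 0% of the markers above the highest Control library in at least 3 knockout libraries only restates the pattern and Control replicate 2 stands apart itself. The sums of 5.85 and 2.63 TPM in Chd4KO replicates 3 and 4, below every Control library, argue against switching-on in all knockout libraries.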

How the results depend on the processing

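Limma's voom on recovered reads and the fit without Chd4KO replicates 2 and 4 were chosen after the data had been seen. All 38 named genes called changed kept their direction in each of the 13 to 19 alternatives that tested them, and 24 of them stayed under the threshold in each. Among the 24, Gpbar1, H2-M10.1, Tcfl5, Gpx6, Gstm3, Slc6a13 and Bcan were under 1 TPM in every Control library. The filter therefore kept them out of each fit that left out a Chd4KO library, so those fits were no check on them. Calls were lost most often for Fcer1g, kept in 7 of 19, and Npy, kept in 8 of 18. The 451 changed genes became 220 (98 higher, 122 lower) at a TPM of at least 5, where fewer genes were tested. They became 700 (445 higher) with median-of-ratios scaling, 755 (466 higher) with quantile normalisation, 784 (498 higher) with voom and 1364 (578 higher, 786 lower) with array weights, and 351 were higher with hormones and mitochondrial genes left out of the scaling. The cause was not tested. The fit without Chd4KO replicates 2 and 4 called 589, of which 351 were lower, and it tested 334 of the 451. Of the 7 gene lists, 3 passed with median-of-ratios scaling and 3 with voom. Left-out libraries gave 135 to 630 changed, 63 to 300 higher and 37 to 330 lower genes, the lowest without Chd4KO replicate 3 or Control replicate 2 and the highest without Chd4KO replicate 4. Because the filter still asked for 4 libraries, the fits with a single library left out tested 352 to 414 of the 451.

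Chd4 came under the threshold with median-of-ratios scaling (-0.92, adjusted p = 0.0122), without hormones and mitochondrial genes in the scaling (-1.11, 0.0194), with quantile normalisation (-0.90, 0.00792), array weights (-0.97, 0.00919), voom (-1.03, 0.00782) and without Chd4KO replicate 4 (-0.91, 0.0376). With a library left out its change ran from -1.37 to -0.91. The median change of the acinar markers turned to -0.90 without Chd4KO replicates 2 and 4 and, with a single library left out, ran from -1.53 without Chd4KO replicate 2 to 2.19 without Control replicate 2. Only 10 of the 15 markers were tested in the fits without Chd4KO replicate 2, so those medians are over fewer genes. The median change of the interferon genes, with a single library left out, ran from -0.40 without Chd4KO replicate 1 to 0.73 without Chd4KO replicate 4, and it was 0.95 without Chd4KO replicates 2 and 4. The cause was not tested for the interferon genes, and the tests on acinar transcripts are given above.

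With the replicate number as a replicate block, 274 genes were called, 158 higher and 116 lower. Changes of libraries with the same number correlated at -0.02 to 0.43, and 1 of the 4 numbers correlated best with its own partner, so the numbers were not taken as pairs. Negative binomial tests, planned for count files only, were not run, since the files hold TPM. At 4 against 4 libraries and this depth, 10.2% of simulated 2-fold changes were recovered, so a gene that did not pass may still have changed.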

Other observations

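The 4 gene lists below, their tests and the count of loci were chosen after the changes had been seen, so their tests may only pose hypotheses. They are one-sided Fisher tests against the other tested genes, adjusted over the 4 lists, and they treat genes as independent. Members below the TPM filter were not tested, and called members were 31.2% of all 16 monoamine genes, 16.7% of all 24 neuropeptide genes, 18.8% of all 48 plasma protein genes and 19.4% of all 36 glutathione genes. A member low in Control enters the test only if it rises, so each list was also tested among genes with a mean Control TPM of at least 1. Genes of monoamine synthesis and breakdown changed more often than others, 5 of 12 tested (41.7%) against 2.94% (adjusted p = 2.01e-05, and 7.89e-06 among genes at that Control level). Besides Tph1, Ddc, which makes serotonin and dopamine, fell from 280.3 ± 21.7 to 128 ± 33.2 TPM (SD, n = 4 each; log2 change -1.17). Maob fell from 265 ± 14.9 to 112 ± 31.9 TPM (-1.27) and Maoa from 5.86 ± 0.701 to 2.53 ± 0.674 TPM (-0.97), both of which break monoamines down. Th, the first enzyme of dopamine synthesis, rose from 37.0 ± 9.02 to 155 ± 39.8 TPM (2.02). Of 10 tested neuropeptide genes 4 changed (40%, adjusted p = 0.00014). Gal and Calca could not have passed the filter on Control values alone, and at that Control level 2 of 8 changed (adjusted p = 0.013). Gal rose from 0.391 ± 0.413 to 10.5 ± 2.79 TPM, Penk from 11.0 ± 3.61 to 49.9 ± 26.6 TPM and Calca from 0.241 ± 0.165 to 1.72 ± 0.484 TPM, while Npy fell. Each of these genes was called by limma (adjusted p of 0.0457 or less).

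Genes of plasma proteins secreted by the liver rose in 9 of 18 tested cases (50%), against 1.48% of other genes (adjusted p = 6.95e-12), and none was called lower. Apof, Fetub, Trf, Serpina1a and Serpina1b among the 9 could not have passed the filter on Control values alone, and among members with a mean Control TPM of at least 1, 4 of 13 rose (adjusted p = 7.89e-06). Besides Ambp and Rbp4, Serpina7, a thyroxine carrier, rose from 18.9 ± 5.20 to 121 ± 13.5 TPM (SD, n = 4 each), Fetub from 0.405 ± 0.131 to 7.46 ± 3.06 TPM, Proc from 2.68 ± 0.971 to 14.9 ± 3.67 TPM and Trf, the iron carrier transferrin, from 0.756 ± 0.378 to 7.69 ± 4.77 TPM. Of 26 tested genes of glutathione enzymes 7 rose (26.9%) against 1.49% of other genes (adjusted p = 1.87e-07), and none was called lower. Gpx6, Gstm3 and Gstm6 among these passed the filter only with their Chd4KO values, and at that Control level 4 of 22 rose (adjusted p = 3.13e-05). Gpx3 rose from 1627 ± 450.4 to 4349 ± 1442 TPM, Gstm2 from 14.4 ± 3.60 to 94.8 ± 28.3 TPM and Gstm7 from 4.33 ± 0.737 to 21.4 ± 3.05 TPM, while Gstm1 of the same cluster was at 68.2 ± 8.70 and 76.0 ± 18.6 TPM and did not pass. Gstm5 of that family lay lower in Chd4KO, at 34.6 ± 1.53 and 21.3 ± 1.56 TPM (limma adjusted p = 0.0556). Gss did as well, at 14.2 ± 1.82 and 7.37 ± 2.03 TPM (limma adjusted p = 0.0633). The groups did not overlap in either gene, but neither passed. Members of the Gstm and Serpina1 families lie side by side and are close copies, so their values are uncertain and not independent. The Gstm cluster alone gave 4 of the 7 genes.

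Changed genes of the same direction lay near each other more often than random sets of tested genes. Of the 233 risen genes, 57 had another risen gene within 100 kb, against 6 to 28 in the central 95% of 1000 random sets. The average density of tested genes therefore does not give this count. The random sets were not matched for local gene density, so they cannot tell whether the risen genes lie in denser regions. Without pairs that overlap or share a family name 29 were left, against 4 to 24, but that count takes some shared loci more than once, and with such genes joined into loci 25 were left, against 4.98 to 24. The 217 fallen genes with a position gave 40 (random sets 4 to 25), 26 (4 to 22) and 20 (4 to 23) in the same 3 counts, so nearness was not particular to genes that rose. At 1 above the bound for risen genes and within it for fallen genes, shared reads are not excluded with any margin, and regulation of neighbouring genes together stays open.

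On chromosome 7 the risen genes included Th (142892752 to 142931128), R74862, Cd81 (143052739 to 143067934), Cdkn1c and Slc22a18, singled out after their values were seen. Cdkn1c, an imprinted inhibitor of the cell cycle, rose from 0.778 ± 0.350 to 3.74 ± 0.994 TPM (SD, n = 4 each; limma adjusted p = 0.0132). Slc22a18, its imprinted neighbour, rose from 1.46 ± 0.237 to 7.11 ± 2.14 TPM (adjusted p = 0.00403), and R74862, which overlaps the start of Cd81, from 8.00 ± 2.56 to 43.5 ± 6.76 TPM. Tssc4 and Kcnq1, which lie between Cd81 and Cdkn1c, did not pass (adjusted p = 0.415 and 0.586), nor did Trpm5 beside Cd81, at 24.9 ± 5.98 and 11.1 ± 3.53 TPM without overlap of the groups (log2 change -1.13, adjusted p = 0.0639), opposite to the risen genes. On chromosome 11 Timp2, an inhibitor of metalloproteinases within 100 kb of C1qtnf1, rose from 4.63 ± 0.795 to 17.7 ± 6.42 TPM.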
